A study of Capra hircus with 6 samples.

How the data were processed

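The samples are longissimus dorsi muscle of Haimen goats, 3 libraries from fetuses at 75 days of gestation and 3 from kids of 1 day, grouped by the sample titles. The labels list the 6 libraries as separate samples but do not state that each comes from a different animal, so p-values measure the spread between these libraries. Per the labels' protocols, total RNA was depleted of ribosomal RNA and treated with RNase R, an enzyme that digests linear RNA. A strand-marked (dUTP) library was then made by PCR and sequenced as paired reads of 150 bases on a NovaSeq instrument. The submitters' processing notes name cutadapt, FastQC and TopHat. The circRNA caller, the genome build, the annotation and their settings are not given in the sources used here.

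The authors deposited a quality table with counts of raw and valid reads per library and percent values (reads kept, GC content, base quality), per the file headers. The deposited circRNA tables hold counts of back-splice reads per circRNA and library, with sequence, start, end, strand, class, exon number, length and host gene, and the authors' normalized signal, SRPBM. In each library SRPBM is the count times one constant, which for a read length of 150 bases implies a library total of 78.2% to 82.4% of the valid reads. The authors' deposited comparison gives a log2 fold change of fetus over kid, computed from the group means of SRPBM, with a p-value and a q-value. The test behind them is not given in the sources used here. The back-splice counts and the counts of the deposited expression file differ at 38 entries of 18 circRNAs; the former were used.

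Valid reads ranged from 34123876 to 52035202 per library and back-splice reads from 33222 to 77111, and 3 reads in the shallowest library correspond to 82.6 CPM for circRNAs and 88.4 CPM for host genes. Where a stage had no read, a fold is given as a lower bound against a floor of 3 reads over the whole group. Where it had 1 to 3 reads, a CPM ratio with an exact 95% interval is given. This CPM ratio is kid over fetus for the reads pooled over each stage, scaled by the pooled library totals with TMM factors. It is not the ratio of the mean CPM. The floor rests on the depth of the group without reads: leaving out fetus 3 there would lower a bound to 55.5% of its value, leaving out kid 1 to 60.7% and leaving out kid 3 to 61.3%. Floors and intervals cover counting error only, since PCR copies are not independent molecules. For 4563 circRNAs the host was given as a gene number, and all 4563 were matched to a symbol in the RefSeq gene table provided with the data. Host genes that stood under more than 1 name (2002) were then joined, giving 6418 host genes. Coordinates are those of the files, with each sequence written as the chromosome that the gene table gives for its genes; 2 sequences not named as chromosomes were taken as X from the genes on them. circRNAs of overlapping genes and of similar gene copies can share reads.

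Counts were tested with edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust settings, glmQLFTest, kid minus fetus). TMM factors, total back-splice reads as library sizes and Benjamini-Hochberg adjustment were used, for circRNAs with at least 5 reads in at least 3 libraries. The same test was run on reads summed over the exonic and intronic circRNAs of a host gene. SE is the absolute log2 fold change divided by the square root of F. The common biological coefficient of variation was 0.420 for circRNAs and 0.275 for host genes. Unequal change among the circRNAs of a host gene was tested with diffSpliceDGE. Gene lists (25 lists, 1335 genes) were tested with camera of limma 3.58.1 at a correlation of 0.01 where at least 5 members were tested. They cover the sarcomere, developmental sarcomere isoforms, calcium handling, the dystrophin complex and costamere, myogenic regulators, cell cycle, matrix, oxidative metabolism, glycogen and glycolysis, insulin, TGF-beta and WNT signalling, chromatin, splicing factors, proteolysis, the neuromuscular junction, hosts from muscle studies and hosts of widely conserved circRNAs. Others hold markers of endothelium, immune, erythroid, fat, nerve, smooth muscle and cartilage, tendon or bone cells. Values per library were compared by exact permutation tests, two-sided, in Python 3.11.15 with scipy 1.17.1. Detection was counted after thinning every library to 33222 reads, as the mean of 20 seeded draws.

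The tests, the gene lists and the rule for naming genes were fixed before the data were examined. Chosen for naming were the 10 circRNAs with the smallest p that rose and the 10 that fell (1 of which is not described), with no overlap between stages, a host symbol that is not a LOC or numbered name and at most 1 per host. Also named are the 10 circRNAs with the highest mean CPM, in each list the 2 risen and 2 fallen members with the smallest p, or the 2 with the most reads where none passed, and the 5 host genes with the smallest p for unequal change. MYH8, further passing members of small groups, and the genes and circRNAs of the other observations were named after their values were seen. The tests were checked on simulated counts with the means and library sizes of these data. Each feature was drawn independently, with the dispersion that these data show on trend at its abundance. Features more variable than this trend were not simulated. For circRNAs (1569 entered the test), 2.41% of those changed 2-fold and 42.7% of those changed 4-fold were recovered, with 0% of the calls wrong. Few 2-fold changes in single circRNAs can thus be recovered at these depths and this spread. For host genes (1594 entered) 21.7% and 74.2% were recovered, with 3.26% of the calls wrong. In simulated host genes, the circRNA with the most reads was raised 8-fold in kid. The test for unequal change recovered 66.7% of these host genes (277 host genes tested, 4.76% of the calls wrong). Smaller changes and changes in less abundant circRNAs were not simulated for this test. With every member of the simulated sarcomere list raised 2-fold, its camera adjusted p was 6.14e-13, and 1 other list was called. Lists with correlated members, or with members that move both ways, were not simulated.

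Alternatives covered median-of-ratios size factors, no TMM, valid reads as library size, the DESeq2 1.42.0 Wald test, and limma with a trend on log2 of SRPBM plus 0.156 or 1.56. They also covered other read filters, stricter thresholds, the replicate number as a block, each library left out, the Simes test, an estimated correlation in camera, fry, other read totals and other detection rules. Chosen after seeing the data were the pairs of identifiers added together, the counts of the expression file, host names as in the files, exonic circRNAs only, the libraries with over 80% valid reads, the read total implied by SRPBM, and class shares without the most abundant intronic circRNAs or the myosin cluster. Replicates were compared before averaging: counts per host gene of 2 libraries of one stage differed by a chi-square of 1.63 to 3.00 per degree of freedom, above counting noise, which does not tell whether they come from different animals.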

Results

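Circular RNAs (circRNAs), closed transcripts made when a downstream splice site is joined back to an upstream one, were profiled in the longissimus dorsi, the long muscle of the back, of Haimen goats. There were 3 libraries from fetuses at 75 days of gestation (fetus) and 3 from kids on day 1 after birth (kid), and the comparison asks which circRNAs differ between these stages. The tables hold 25500 circRNAs: 22285 are exonic, 2596 lie within an intron and 619 are assigned to no single gene. The fetus libraries held 36484, 33222 and 56467 back-splice reads and the kid libraries 77111, 42695 and 73922. Entries are counted as listed, with 1463 pairs that start 1 base apart kept separate. Detection was sparse: 8736 circRNAs had 1 read in total, and 1435 were seen in all 6 libraries. Levels are given as CPM, counts scaled to the library's total with TMM factors, as mean ± SD (n = 3 per stage). Changes are given as log2 of kid over fetus ± SE, with adjusted p from edgeR's quasi-likelihood test (Benjamini-Hochberg).

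Summed per host gene, circular RNA of the thin filament gene NEB was 5.96-fold and that of the ubiquitin ligase gene UBE3A 3.28-fold higher in kid, and ACACB, an acetyl-CoA carboxylase gene of muscle and fat, was 10.4-fold higher. The collagen gene COL12A1 was 11.0-fold lower, with 67 reads in fetus and 8 in kid, and the growth factor gene TGFB2 3.37-fold lower. Of 1755 host genes tested, 337 passed an adjusted p of 0.05, 193 higher in kid and 144 lower, and 299 of them differed at least 2-fold. The CPM of the stages did not overlap in 330 of the 337; over all tested host genes this held for 37.0%, against 10% by chance. These values measure circular RNA of a gene and not its mRNA. Scaled to total back-splice reads without TMM, 135 host genes were higher and 203 lower, and the median log2 fold change of all tested host genes moved to -0.20. The fits that left out 1 library called 184 (without fetus 1), 200 (without fetus 2), 210 (without kid 2) and up to 248 host genes, and a fit scaled to valid reads 200. Libraries fetus 1 and fetus 2 kept 70.7% and 69.1% of their reads after trimming, and the other 4 libraries 84.0% to 87.9%. With fetus 3 alone against the 3 kid libraries, a fit chosen after seeing the data, 68 host genes passed (51 higher, 17 lower).

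Of the named host genes, many were not called in some alternatives. Scaled to valid reads, RYR3, ITPR2, DMD, NFIX, ORC4, TBC1D4, RICTOR, IGF2R, RYK, SMARCC1, IGF2BP3, ESYT2, CAMSAP1, DOCK9, DOCK8, EBF2, FHOD3, DTNA, PHKB, MCCC1, FBN2 and LAMB1 did not pass (adjusted p = 0.0512 to 0.265). With DESeq2, RYR3, ITPR2, NFIX, ORC4, TBC1D4, IGF2R, RYK, DOT1L, SMARCC1, IGF2BP3, DOCK9, DOCK8, EBF2, FHOD3, DTNA, MCCC1 and LAMB1 did not pass (adjusted p = 0.0539 to 0.140), and without TMM NFIX, ORC4, DOT1L, DTNA, PHKB, MCCC1 and PTPN4 did not (adjusted p = 0.0548 to 0.0740). Without a read filter RYR3, ITPR2, TBC1D4, IGF2R, RYK, SMARCC1, IGF2BP3, CAMSAP1, DOCK8, EBF2, FHOD3, MCCC1 and LAMB1 did not pass (adjusted p = 0.0618 to 0.245). With host names as in the files, which divides the reads of a gene over its names, RYR3, ITPR2, NFIX, ORC4, KIF20A, OGDH, TBC1D4, RYK, SMARCC1, DOCK8, EBF2, DTNA, MCCC1, LAMB1 and PTPN4 did not pass (adjusted p = 0.0554 to 0.328). With the replicate number as a block this held for ITPR2, SMARCC1, EBF2, MCCC1 and LAMB1 (adjusted p = 0.0513 to 0.0715), with the counts of the expression file for ITPR2, SMARCC1 and EBF2 (adjusted p = 0.0503 to 0.0509), and over exonic circRNAs only for SMARCC1 and PTPN4 (adjusted p = 0.0533 to 0.0849). In fetus 3 alone against the 3 kid libraries, CMYA5, PDLIM7, CACNA2D1, RYR3, ITPR2, DMD, ANK2, NFIX, ORC4, KIF20A, TBC1D4 and INSR did not pass. Nor did RICTOR, IGF2R, RYK, DOT1L, SMARCC1, ADARB1, ARHGAP10, ESYT2, CAMSAP1, DOCK9, DOCK8, DTNA, PHKA1, PHKB and MCCC1. FBN2, LAMB1, UBR3, FBXL17, PTPN4, BNC2, ELF1 and PHLPP1 did not pass either. The log2 fold change of DOT1L was 3.19 there and that of ORC4 1.10. Named host genes with few reads in kid, such as COL12A1, POSTN, MYL4, LMNB1, IGF2BP3 and EBF2, could not enter this fit and were not tested in it.

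**Figure D1:**
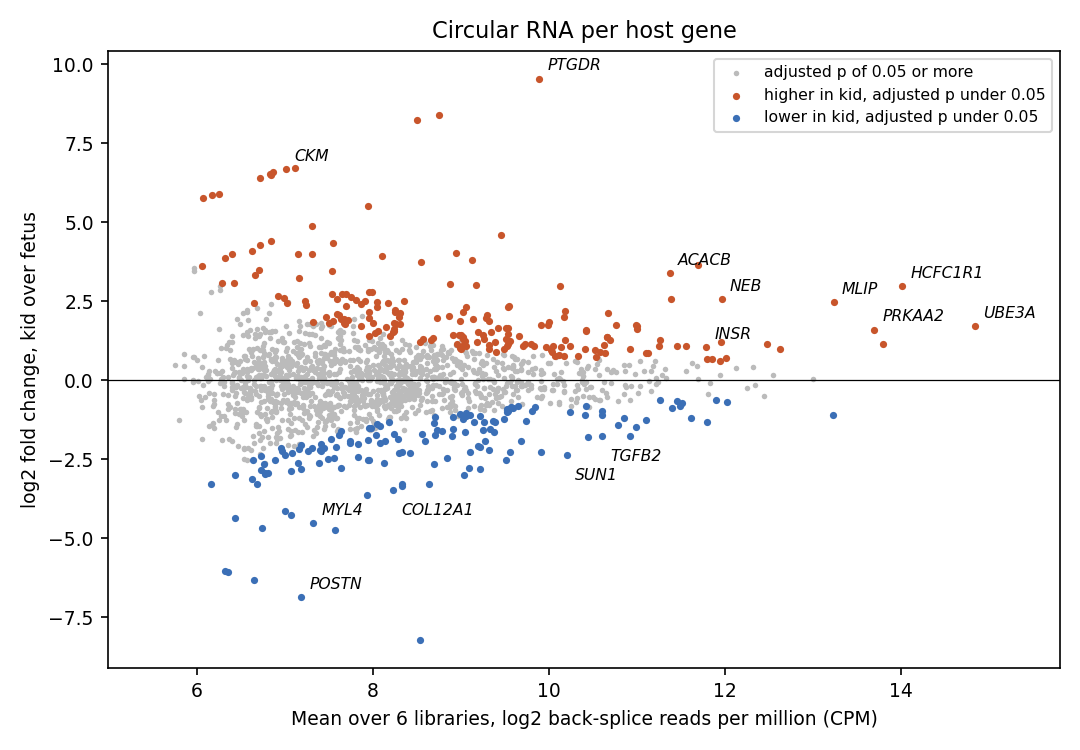
Circular RNA per host gene, with the mean over 6 libraries on the x axis (log2 CPM) and the log2 fold change, kid over fetus, on the y axis; red and blue points passed an adjusted p of 0.05, 193 higher and 144 lower in kid. Points of genes with no read in one stage, such as PTGDR, CKM and POSTN, sit at a fitted value that depends on the prior count.

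Of 18 tested sarcomere genes, 6 rose, 3 fell and 9 did not pass (6 risen and 3 fallen adjusted over the list alone, camera adjusted p = 0.272). NEB, which encodes nebulin of the thin filament, stood at 1140.0 ± 296 CPM in fetus and 6839 ± 1479 CPM in kid (log2 fold change 2.58 ± 0.23, adjusted p = 7.43e-08). CMYA5, which encodes the myospryn protein of striated muscle, stood at 425 ± 62.7 CPM in fetus and 1493 ± 624 CPM in kid (log2 fold change 1.76 ± 0.32, adjusted p = 5.12e-04). MYL4, the embryonic and atrial myosin light chain, had 43 reads in fetus and 2 in kid (adjusted p = 6.40e-04), both kid reads in kid 1. This is a CPM ratio of 0.0351 with an exact 95% counting interval of 0.00412 to 0.135, and the fitted log2 fold change was -6.87 without kid 1 and -3.88 without kid 3. PDLIM7, a PDZ and LIM domain protein of the actin cytoskeleton, stood at 621 ± 195 CPM in fetus and 152 ± 127 CPM in kid (log2 fold change -1.93 ± 0.48, adjusted p = 0.00671). Among the fits that left out 1 library, PDLIM7 did not pass without fetus 3 (highest adjusted p = 0.0517), and its log2 fold change was -2.78 without kid 1. The other fallen member was FHOD3, but with 1 library left out FHOD3 passed in 2 of 6 fits, without fetus 3 or kid 1 (adjusted p = 0.0133 to 0.115). Of the developmental sarcomere isoforms, 2 genes were tested, MYL4, which fell, and MYH8, the perinatal myosin heavy chain, which did not pass (0 risen and 1 fallen adjusted over the list alone). MYH8 had 8 reads in fetus and 18 in kid (log2 fold change 0.69 ± 0.92, adjusted p = 0.661), not counting circRNAs that join it to a neighbouring gene.

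Of 14 tested calcium handling genes, 3 rose, 2 fell and 9 did not pass (3 risen and 2 fallen adjusted over the list alone, camera adjusted p = 0.272). ATP2A1, the calcium pump SERCA1 of fast fibres, stood at 948 ± 189 CPM in fetus and 3145 ± 1089 CPM in kid (log2 fold change 1.72 ± 0.26, adjusted p = 8.89e-05). CACNA2D1, a subunit of the voltage-gated calcium channel, rose (log2 fold change 1.58 ± 0.26, adjusted p = 2.14e-04), as did the chloride channel gene CLCN1. The calcium release channel genes RYR3 (log2 fold change -1.16 ± 0.36, adjusted p = 0.0293) and ITPR2 (log2 fold change -1.33 ± 0.47, adjusted p = 0.0488) fell. With 1 library left out, RYR3 passed in 2 of 6 fits, without fetus 2 or kid 3 (adjusted p = 0.0381 to 0.176), and ITPR2 passed in 1 of 6 fits, without kid 2 (adjusted p = 0.0428 to 0.184). The log2 fold change of CLCN1 was 4.77 without fetus 1 and 2.95 without fetus 3. The dystrophin complex and the costamere tie the sarcomere to the membrane, and of 16 tested members 3 rose, 1 fell and 12 did not pass (4 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.287). LMO7, a LIM domain protein, stood at 925 ± 26.7 CPM in fetus and 3129 ± 287 CPM in kid (log2 fold change 1.75 ± 0.22, adjusted p = 1.11e-05). DMD, the gene of dystrophin, stood at 728 ± 19.8 CPM in fetus and 1528 ± 77.5 CPM in kid (log2 fold change 1.06 ± 0.25, adjusted p = 0.00475), and the dystrobrevin gene DTNA also rose. When 1 library was left out, DTNA passed in 2 of 6 fits, without fetus 2 or kid 2 (adjusted p = 0.0222 to 0.177), and its log2 fold change was 2.24 without fetus 2. Scaled to valid reads, DMD did not pass (adjusted p = 0.0621). ANK2, the gene of ankyrin B, fell (log2 fold change -1.56 ± 0.34, adjusted p = 0.00261).

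Among 14 tested genes of glycogen and glycolysis, 4 rose, 2 fell and 8 did not pass (5 risen and 2 fallen adjusted over the list alone, camera adjusted p = 0.119). PRKAA2, the catalytic alpha 2 subunit of the energy sensor AMPK, stood at 6551 ± 396 CPM in fetus and 19903 ± 2879 CPM in kid (log2 fold change 1.60 ± 0.16, adjusted p = 5.42e-07). CKM, the muscle creatine kinase, had 0 reads in fetus and 42 in kid, at least 11.1-fold higher against a floor of 3 reads over the fetus group (adjusted p = 5.59e-04). The phosphorylase kinase genes PHKA1 and PHKB rose as well, but with 1 library left out PHKB passed in 3 of 6 fits, without fetus 1, kid 1 or kid 3 (adjusted p = 0.0119 to 0.106). PGM5, a structural protein of the phosphoglucomutase family that lacks the enzyme's activity, stood at 2575 ± 194 CPM in fetus and 959.8 ± 346 CPM in kid (log2 fold change -1.40 ± 0.25, adjusted p = 4.26e-04). TBC1D4, a regulator of glucose transporter traffic, fell (log2 fold change -1.45 ± 0.46, adjusted p = 0.0336), but with 1 library left out TBC1D4 passed in 0 of 6 fits (adjusted p = 0.0515 to 0.131). Of 20 tested oxidative metabolism genes, 3 rose, 0 fell and 17 did not pass (2 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.217). OXCT1, which starts the use of ketone bodies, stood at 608 ± 117 CPM in fetus and 2662 ± 792 CPM in kid (log2 fold change 2.13 ± 0.27, adjusted p = 1.24e-05). OGDH of the citric acid cycle stood at 58.0 ± 78.5 CPM in fetus and 343 ± 95.6 CPM in kid (log2 fold change 2.74 ± 0.75, adjusted p = 0.0133). In the fits that left out 1 library, OGDH did not pass without fetus 1 or fetus 3 (highest adjusted p = 0.0699). Its log2 fold change was 4.71 without fetus 2 and 1.96 without fetus 3. The other risen member was MCCC1, an enzyme of leucine breakdown. With 1 library left out, MCCC1 passed in 1 of 3 fits, without fetus 1 (adjusted p = 0.0229 to 0.132), and its log2 fold change was 6.03 without fetus 1 and 2.33 without fetus 3.

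Of 20 tested genes of insulin, IGF and mTOR signalling, 1 rose, 3 fell and 16 did not pass (1 risen and 5 fallen adjusted over the list alone, camera adjusted p = 0.369). INSR, the insulin receptor, stood at 2311 ± 169.9 CPM in fetus and 4756 ± 356 CPM in kid (log2 fold change 1.04 ± 0.19, adjusted p = 4.92e-04). RICTOR, a subunit of the second mTOR complex, stood at 814 ± 77.5 CPM in fetus and 319 ± 46.9 CPM in kid (log2 fold change -1.33 ± 0.32, adjusted p = 0.00567), but did not pass when scaled to valid reads (adjusted p = 0.0670). IGF2R, the receptor that clears IGF2, fell (log2 fold change -1.35 ± 0.40, adjusted p = 0.0202), as did IGF2BP3. When 1 library was left out, IGF2R passed in 2 of 6 fits, without fetus 2 or kid 3 (adjusted p = 0.0158 to 0.107). In the TGF-beta, BMP and activin list, 0 rose, 1 fell and 14 did not pass of 15 tested (0 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.806). TGFB2, the ligand TGF-beta 2, stood at 2406 ± 341 CPM in fetus and 709 ± 228 CPM in kid (log2 fold change -1.75 ± 0.26, adjusted p = 7.58e-05). In the WNT list, 0 rose, 1 fell and 8 did not pass of 9 tested (1 risen and 1 fallen adjusted over the list alone, camera adjusted p = 0.781). RYK, a WNT receptor, fell (log2 fold change -0.84 ± 0.28, adjusted p = 0.0388). When 1 library was left out, RYK passed in 1 of 6 fits, without kid 1 (adjusted p = 0.0308 to 0.130).

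**Figure D2:**
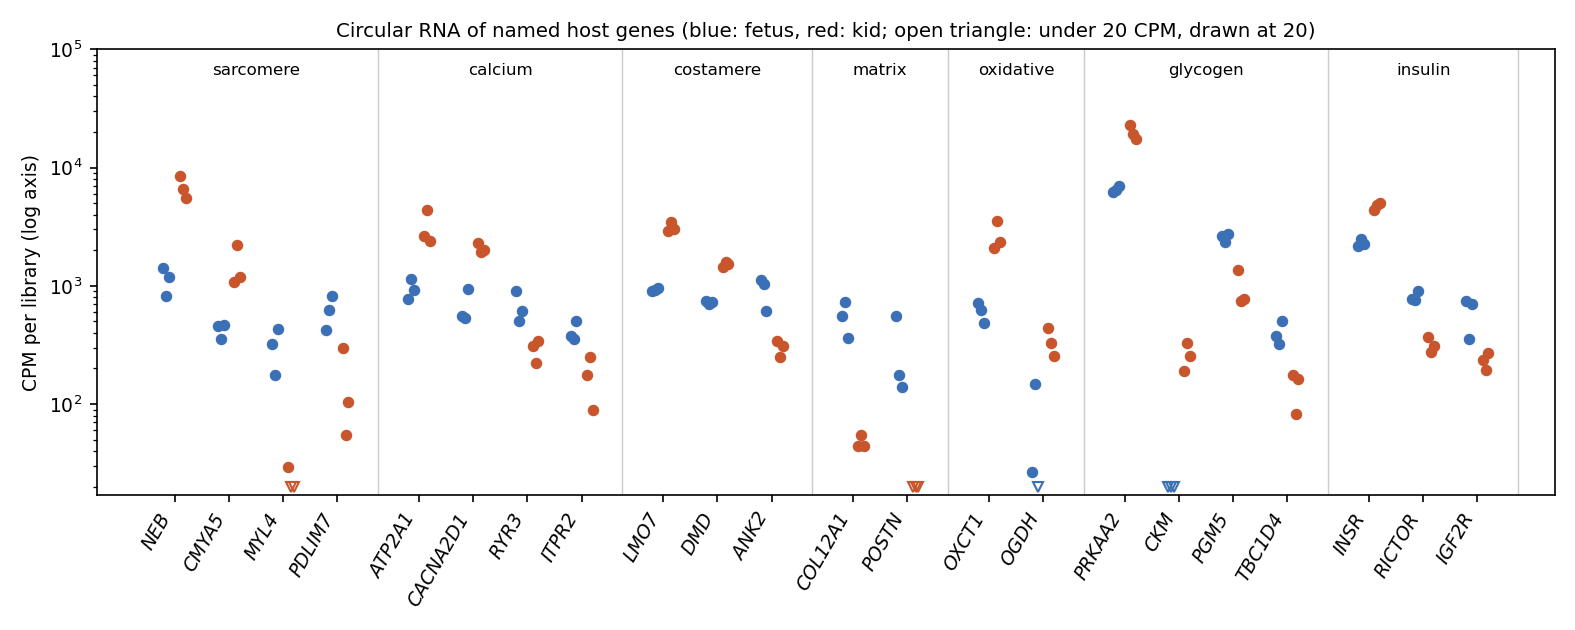
CPM of named host genes in each library on a log axis, grouped by gene list, with 1 point per library (blue: 3 fetus, red: 3 kid). Open triangles mark libraries under 20 CPM, as in the 3 fetus libraries of CKM and the 3 kid libraries of POSTN, where no read was counted.

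Of 24 tested genes of the extracellular matrix and fibroblasts, 0 rose, 5 fell and 19 did not pass (0 risen and 5 fallen adjusted over the list alone, camera adjusted p = 0.0873). COL12A1, a collagen associated with fibrils, stood at 554 ± 186 CPM in fetus and 48.1 ± 6.23 CPM in kid (log2 fold change -3.46 ± 0.54, adjusted p = 9.54e-05). It had 67 reads in fetus and 8 in kid. The kid libraries held 3, 2 and 3 of these, so the small SD in kid does not show counting error. POSTN, the gene of periostin, had 35 reads in fetus and 0 in kid, at least 16.6-fold lower against a floor of 3 reads over the kid group (adjusted p = 5.88e-04). Fetus 1 held 21 of these reads, and without it the bound was 1.85 times lower. The other fallen members were COL21A1, FBN2 and LAMB1, but with 1 library left out LAMB1 passed in 0 of 6 fits (adjusted p = 0.0556 to 0.118). The fitted log2 fold change of COL21A1 was -4.06 without kid 1 and -6.29 without kid 3. Of 16 tested cell cycle genes, 1 rose, 2 fell and 13 did not pass (1 risen and 2 fallen adjusted over the list alone, camera adjusted p = 0.287). LMNB1, the gene of lamin B1, stood at 291 ± 99.0 CPM in fetus and 43.8 ± 16.0 CPM in kid (log2 fold change -2.63 ± 0.64, adjusted p = 0.00592). It had 40 reads in fetus and 8 in kid. KIF20A, a mitotic kinesin, fell (log2 fold change -2.30 ± 0.60, adjusted p = 0.0103) and ORC4, of the origin recognition complex, rose (log2 fold change 1.88 ± 0.60, adjusted p = 0.0324). In the fits that left out 1 library, KIF20A did not pass without fetus 2 (highest adjusted p = 0.0578), and ORC4 passed in 2 of 6 fits, without fetus 3 or kid 2 (adjusted p = 0.0184 to 0.111). The log2 fold change of KIF20A was -3.06 without kid 1 and -1.61 without kid 3, and that of ORC4 2.78 without fetus 3. Of 15 tested myogenic regulators, 1 rose, 0 fell and 14 did not pass (1 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.781). NFIX, a transcription factor of fetal myogenesis, stood at 291 ± 209 CPM in fetus and 751 ± 143 CPM in kid (log2 fold change 1.36 ± 0.41, adjusted p = 0.0235). Among the fits that left out 1 library, NFIX passed in 3 of 6 fits, without fetus 1, kid 1 or kid 2 (adjusted p = 0.0108 to 0.119).

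In the proteolysis and autophagy list, 5 rose, 0 fell and 31 did not pass of 36 tested (5 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.217). UBE3A was the host gene with the highest mean CPM, with 13625 ± 301 CPM in fetus and 44716 ± 7448 CPM in kid (log2 fold change 1.71 ± 0.15, adjusted p = 6.28e-08). A single circRNA of 3 exons held 1683 of the 1765 UBE3A reads in fetus and 7216 of 7382 in kid. USP13, a deubiquitinase, stood at 1014 ± 151 CPM in fetus and 3091 ± 361 CPM in kid (log2 fold change 1.63 ± 0.23, adjusted p = 2.98e-05), and UBR3, UBE2D1 and FBXL17 also rose. Of 42 tested chromatin regulators, 2 rose, 1 fell and 39 did not pass (1 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.781). SATB1, a chromatin organiser, rose (log2 fold change 1.39 ± 0.33, adjusted p = 0.00541), as did the histone methyltransferase gene DOT1L (log2 fold change 1.91 ± 0.62, adjusted p = 0.0364), while SMARCC1 of the BAF complex fell (log2 fold change -0.81 ± 0.28, adjusted p = 0.0476). Over the fits that left out 1 library, DOT1L passed in 2 of 6 fits, without fetus 1 or kid 2 (adjusted p = 0.0211 to 0.167), and SMARCC1 passed in 0 of 6 fits (adjusted p = 0.0512 to 0.147). The log2 fold change of DOT1L was 2.55 without fetus 1. Of 25 tested splicing and RNA-binding factors, 1 rose, 1 fell and 23 did not pass (1 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.661). ADARB1, an adenosine deaminase that edits RNA, stood at 61.5 ± 31.6 CPM in fetus and 448 ± 30.2 CPM in kid (log2 fold change 2.80 ± 0.54, adjusted p = 7.13e-04). IGF2BP3, an RNA-binding protein of fetal tissues, had 21 reads in fetus and 3 in kid, a CPM ratio of 0.108 with an exact 95% counting interval of 0.0206 to 0.361 (adjusted p = 0.0312). With 1 library left out, IGF2BP3 passed in 1 of 3 fits, without kid 1 (adjusted p = 0.0376 to 0.0978), and its fitted log2 fold change was -3.72 without kid 1 and -2.43 without kid 3.

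Of 5 tested genes of the neuromuscular junction, 0 rose, 0 fell and 5 did not pass by edgeR (0 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.781), and 0 had an unadjusted p under 0.05. SYNE1, a nuclear envelope protein, stood at 1065 ± 126 CPM in fetus and 857 ± 299.8 CPM in kid (log2 fold change -0.27 ± 0.29, adjusted p = 0.564), and UTRN, the dystrophin relative utrophin, at 679 ± 65.3 CPM in fetus and 500.4 ± 123 CPM in kid (log2 fold change -0.40 ± 0.32, adjusted p = 0.418). Among hosts of circRNAs named in earlier muscle studies, 4 rose, 0 fell and 14 did not pass of 18 tested (5 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.0873); NEB, LMO7, INSR and the phosphatase gene PTPN4 rose. With 1 library left out, PTPN4 passed in 3 of 6 fits, without fetus 3, kid 2 or kid 3 (adjusted p = 0.00277 to 0.166), and its log2 fold change was 2.99 without fetus 3 and 1.07 without kid 1. Among hosts of widely conserved circRNAs, 4 rose, 2 fell and 28 did not pass of 34 tested (4 risen and 2 fallen adjusted over the list alone, camera adjusted p = 0.781); camera's direction was up and the median log2 fold change -0.13. ARHGAP10, a regulator of small GTPases, stood at 4226 ± 111 CPM in fetus and 8412 ± 282 CPM in kid (log2 fold change 0.99 ± 0.17, adjusted p = 2.39e-04), and LMO7, BNC2 and ELF1 also rose. ESYT2 (log2 fold change -1.70 ± 0.45, adjusted p = 0.0105) and CAMSAP1 (log2 fold change -0.67 ± 0.18, adjusted p = 0.0135) fell. In the fits that left out 1 library, ESYT2 did not pass without fetus 1 (highest adjusted p = 0.0625), and CAMSAP1 did not pass without fetus 1 or kid 1 (highest adjusted p = 0.0657).

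Markers of other cell types were thinly covered. Of 5 tested endothelial genes, 1 rose, 0 fell and 4 did not pass (2 risen and 0 fallen adjusted over the list alone, camera adjusted p = 0.438). DOCK9, a guanine nucleotide exchange factor, stood at 151 ± 20.5 CPM in fetus and 456 ± 156 CPM in kid (log2 fold change 1.57 ± 0.45, adjusted p = 0.0171). The immune list had 1 tested member, DOCK8, which fell (log2 fold change -1.50 ± 0.50, adjusted p = 0.0409). Over the fits that left out 1 library, DOCK9 passed in 3 of 6 fits, without fetus 3, kid 2 or kid 3 (adjusted p = 0.0171 to 0.109), and DOCK8 passed in 1 of 6 fits, without fetus 2 (adjusted p = 0.0495 to 0.163). Of 3 tested adipocyte genes, 1 rose, 1 fell and 1 did not pass (1 risen and 1 fallen adjusted over the list alone). ACACB, which muscle also expresses, stood at 465 ± 128 CPM in fetus and 4845 ± 1150.2 CPM in kid (log2 fold change 3.38 ± 0.27, adjusted p = 1.53e-08). EBF2, a transcription factor of fat precursors, fell (log2 fold change -2.14 ± 0.74, adjusted p = 0.0479), but with 1 library left out EBF2 passed in 1 of 6 fits, without kid 3 (adjusted p = 0.0451 to 0.171), and its log2 fold change was -2.74 without kid 3. Of 3 tested smooth muscle and pericyte genes 0 passed over all host genes and 1 adjusted over the list alone. Among them, ABCC9 had a log2 fold change of 0.70 (adjusted p = 0.0579) and EBF1 of 0.49 (adjusted p = 0.481). ABCC9 passed without kid 3 (log2 fold change 0.85, adjusted p = 0.0388) and over exonic circRNAs only (adjusted p = 0.0476). Of 2 tested nerve and Schwann cell genes 0 passed (0 risen and 0 fallen adjusted over the list alone), NRCAM (-1.43, adjusted p = 0.126) and ANK3 (1.35, adjusted p = 0.169). NRCAM passed without kid 1 (log2 fold change -2.62, adjusted p = 0.0287). The erythroid list and the cartilage, tendon and bone list had 1 tested member each, and neither passed, also adjusted over the list alone: CAT (0.84, adjusted p = 0.509) and THBS4 (0.52, adjusted p = 0.718). Of the 7 lists with under 5 tested members no list was tested as a whole.

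Tested as whole lists against all other host genes, 0 of 18 passed camera with its preset correlation. The smallest adjusted p was 0.0873, for the matrix list downward and the hosts from muscle studies upward, and 4 lists had an unadjusted p under 0.05. With an estimated correlation 0 passed as well (smallest adjusted p = 0.395). By fry, which asks only whether a list's own genes move one way on balance, 7 lists passed (adjusted p = 0.0233 to 0.0343). Upward these were oxidative metabolism, glycogen and glycolysis, proteolysis and autophagy, calcium handling, the hosts from muscle studies and the dystrophin complex, and downward the matrix list. fry was run with TMM only, and its outcome depends on the scaling. The median log2 fold changes of the upward lists ran from 0.25 to 0.79. Without TMM the median of all tested host genes moved to -0.20.

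**Figure D3:**
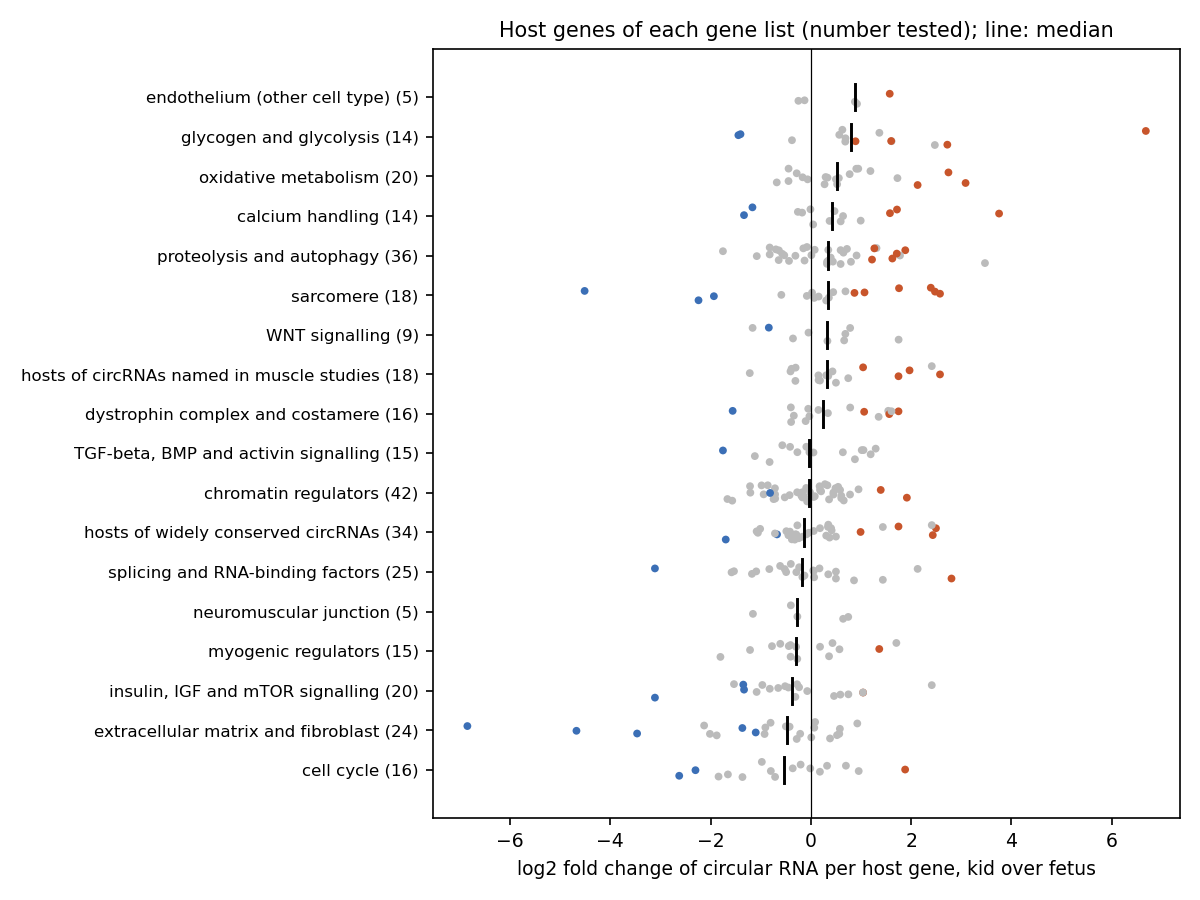
log2 fold change, kid over fetus, of each tested host gene (points) in the gene lists with at least 5 tested members, with the number tested in brackets and the list's median as a black line; red points rose and blue points fell at an adjusted p of 0.05, and grey points did not pass. The medians run from -0.54 in the cell cycle list to 0.88 in the endothelial list.

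At the level of single circRNAs, the one with the highest mean CPM came from 3 exons of UBE3A (chromosome 21, 1519363 to 1525199), and it rose from 12480.4 ± 481 CPM in fetus to 40752 ± 5168 CPM in kid (log2 fold change 1.71 ± 0.12, adjusted p = 4.48e-05). An intronic circRNA of HCFC1R1 (chromosome 25, 2320770 to 2320981) stood at 3383 ± 878 CPM in fetus and 24745 ± 665 CPM in kid (log2 fold change 2.87 ± 0.19, adjusted p = 4.48e-05). Exonic circRNAs of PRKAA2 (chromosome 3, 31268676 to 31285372) and ARHGAP10 (chromosome 17, 60720268 to 60747148) rose by log2 fold changes of 1.70 ± 0.17 (adjusted p = 4.63e-04) and 1.47 ± 0.17 (adjusted p = 9.42e-04). One of SLC9A2, a sodium and proton exchanger (chromosome 11, 7260854 to 7261056), rose by 3.23 ± 0.29 (adjusted p = 3.68e-04). Those of ANO5, a protein of muscle membrane repair (chromosome 29, 21943942 to 21956670), and of ACACB (chromosome 17, 7228667 to 7231913) rose by 3.65 ± 0.34 (adjusted p = 4.09e-04) and 3.91 ± 0.37 (adjusted p = 4.09e-04). A circRNA of PTGDR, a prostaglandin D2 receptor (chromosome 10, 57881637 to 57881971), had 0 reads in fetus and 293 in kid, at least 78.3-fold higher (adjusted p = 4.14e-04). An intronic circRNA of PPP1R12B, a myosin phosphatase subunit (chromosome 16, 78739186 to 78739754), had 0 and 134 reads, at least 33.8-fold higher (adjusted p = 5.89e-04). The remaining one of the 10 risen circRNAs with the smallest p came from MLIP and has a partner entry.

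Lower in kid was an exonic circRNA of SUN1, which links the nucleus to the cytoskeleton (chromosome 25, 42458071 to 42470677), which stood at 1824 ± 381 CPM in fetus and 329 ± 9.55 CPM in kid (log2 fold change -2.46 ± 0.25, adjusted p = 4.63e-04). One of PIEZO2, a mechanically gated channel (chromosome 24, 42654784 to 42656566), had a log2 fold change of -3.56 ± 0.45 (adjusted p = 0.00134), with 79 reads in fetus and 9 in kid. Those of TGFB2 (chromosome 16, 20428760 to 20432602) and of the axon guidance gene SEMA3A (chromosome 4, 83767171 to 83770631) had log2 fold changes of -1.88 ± 0.26 (adjusted p = 0.00243) and -2.71 ± 0.39 (adjusted p = 0.00272). That of the kinase gene STK10 (chromosome 20, 3968039 to 3975194) had one of -2.32 ± 0.34 (adjusted p = 0.00327). GYG2, a glycogenin (chromosome X, 65549200 to 65552397), had 68 reads in fetus and 3 in kid (adjusted p = 0.00200), a CPM ratio of 0.0326 (exact 95% counting interval 0.00656 to 0.0994). Its fitted log2 fold change was -5.50 without kid 1. WNK3, a kinase of ion transport (chromosome X, 23980462 to 23982425), had 48 and 2 (adjusted p = 0.00256), a ratio of 0.0308 (0.00363 to 0.117). Of the 10 fallen circRNAs with the smallest p, 1 is not described, and the entries from MLIP and FOXJ3 have partner entries.

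Among the 10 circRNAs with the highest mean CPM, one of LOC102191280 (chromosome 21, 65000513 to 65014965) stood at 8141 ± 423 CPM in fetus and 16718 ± 1898 CPM in kid (log2 fold change 1.04 ± 0.13, adjusted p = 0.00113), but did not pass in limma with the smaller pseudocount (adjusted p = 0.0896). A circRNA assigned to no single gene (chromosome 19, 29151328 to 29251136) spans much of the myosin heavy chain gene cluster. It had 7 reads in fetus and 3543 in kid, 1809 of them in kid 2, and stood at 23035 ± 19309 CPM in kid (log2 fold change 8.69 ± 1.32, adjusted p = 0.0218). Its log2 fold change was 9.9996 without fetus 2 and 7.84 without kid 2. Without a read filter it did not pass (adjusted p = 0.231). Another without a host gene (chromosome X, 6635395 to 6636857) fell, from 17236 ± 2316 CPM in fetus to 1296 ± 514 CPM in kid (log2 fold change -3.72 ± 0.27, adjusted p = 6.26e-05). A second PRKAA2 circRNA (chromosome 3, 31281644 to 31285372) rose as well (log2 fold change 1.40 ± 0.15, adjusted p = 5.66e-04). The other 3 did not pass in the edgeR fit described. One of LOC106503383 (chromosome 21, 65156181 to 65159681) stood at 11334 ± 869 CPM in fetus and 4555 ± 3005 CPM in kid (log2 fold change -1.32 ± 0.40, adjusted p = 0.0808). It did pass scaled to valid reads, with DESeq2, both limma fits, no read filter and the replicate number as a block (adjusted p = 3.92e-07 to 0.0476), and without kid 2 (log2 fold change -1.96, adjusted p = 2.55e-04). One of ZEB1, a transcriptional repressor (chromosome 13, 33258516 to 33272240), stood at 7029 ± 789 CPM in fetus and 7349 ± 903 CPM in kid (log2 fold change 0.06 ± 0.15, adjusted p = 0.849). One of MYBPC1, the slow myosin-binding protein C (chromosome 5, 64143969 to 64145981), stood at 5157 ± 452 CPM in fetus and 4829.7 ± 1668 CPM in kid (log2 fold change -0.09 ± 0.23, adjusted p = 0.853). The signs of these last 2 small differences changed between scalings. With the reads of entries 1 base apart added together, a circRNA of MLIP took the place of that of MYBPC1 among the 10.

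Over all 1904 tested circRNAs, 226 passed an adjusted p of 0.05, 132 higher in kid and 94 lower. In each of the 226 the CPM of the stages did not overlap (36.2% of all tested, against 10% by chance). Among 122 tested intronic circRNAs 21 rose and 4 fell, against 105 and 82 among 1732 exonic ones (Fisher's exact test across circRNAs, which are not independent replicates, two-sided p = 0.00855). Without TMM 114 were higher and 124 lower, with the median log2 fold change at -0.16, and a fit scaled to valid reads called 137. Leaving out any of the 6 libraries lowered the count, to 85 (without fetus 2) to 135 (without fetus 3). In fetus 3 alone against the 3 kid libraries, the named circRNAs of UBE3A, ANO5, ACACB, PTGDR, PRKAA2 (both), ARHGAP10, TGFB2, SEMA3A, STK10 and LOC102191280 did not pass. The one that spans the myosin cluster did not pass either. Named circRNAs with few reads in kid, such as those of PIEZO2, GYG2 and WNK3, could not enter that fit.

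Many circRNAs are listed under 2 identifiers: 1463 pairs of entries share host gene, strand and end and start 1 base apart, the host written once as a symbol and once as a gene number. With the reads of each pair added together, a step chosen after seeing the data, 300 of 1962 circRNAs passed, 185 higher and 115 lower. For MLIP, which encodes a lamin-interacting protein of muscle, the entry starting at 42354033 (chromosome 23, end 42365085) had 0 reads in fetus and 1662 in kid. The entry starting at 42354034 had 120 in fetus and 0 in kid. Each passed alone, in opposite directions (adjusted p = 2.04e-06 and 5.89e-04). Added together they stood at 930.3 ± 309 CPM in fetus and 9404 ± 780.0 CPM in kid (log2 fold change 3.35 ± 0.24, adjusted p = 5.92e-06). For FOXJ3, a transcription factor gene, the entry among the 10 that fell (chromosome 3, 16859499 to 16898215; adjusted p = 0.00346) did not pass with its partner's reads added (log2 fold change 0.09 ± 0.42, adjusted p = 0.925). Of the 226 circRNAs that passed as listed, 18 have a partner entry. With the pair added 14 of these passed, though not always in the same direction, as in MLIP. Totals per host gene hold both members.

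**Figure D4:**
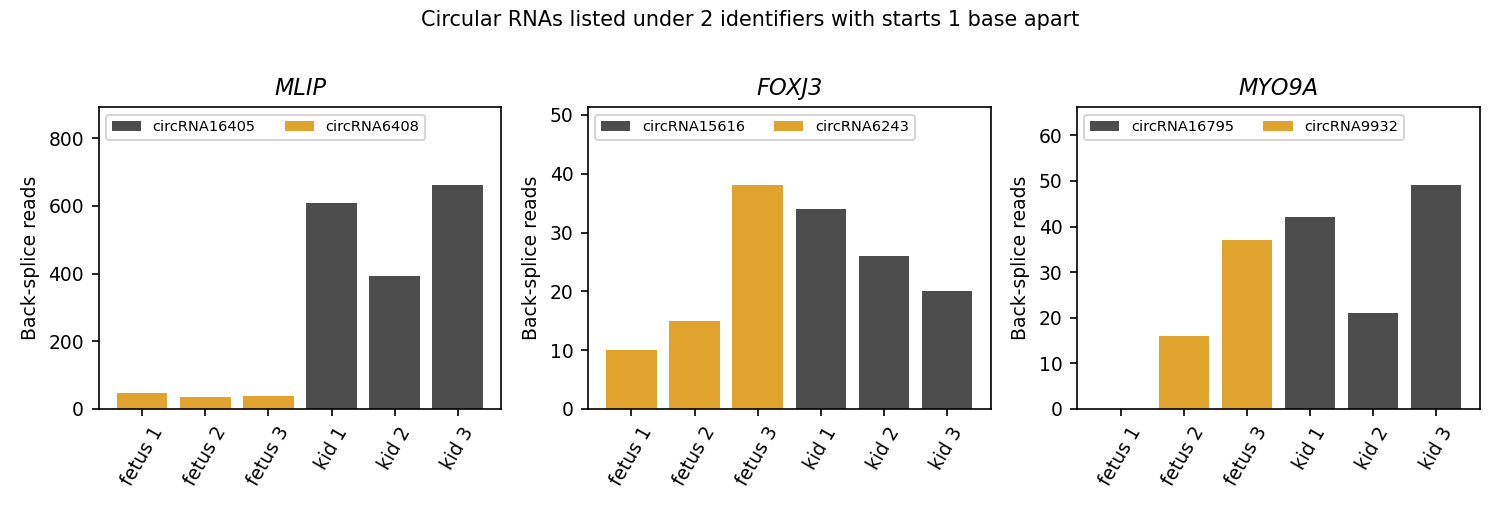
Back-splice reads per library (y axis) of circRNAs of MLIP, FOXJ3 and MYO9A that are listed under 2 identifiers with starts 1 base apart, stacked in grey and yellow. In each library at most 1 of the 2 identifiers has reads; in MLIP the fetus libraries hold 35 to 48 reads and the kid libraries 393 to 660.

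Circular RNAs of one host gene were tested for unequal change. In ACTN2, the gene of alpha-actinin 2 of the Z-disc, a 3-exon circRNA (chromosome 28, 36019292 to 36024468) had 34 reads in fetus and 0 in kid, at least 14.8-fold lower. A 6-exon circRNA with the same start (end 36034542) had 5 reads in fetus, all in fetus 1, and 35 in kid, and did not pass alone (adjusted p = 0.231). The test for unequal change passed (gene-level adjusted p = 0.00319, and 0.00133 with pairs added). In LOC102168946, log2 fold changes ran from -2.69 ± 0.87 (chromosome 21, 65123075 to 65127781) to 0.67 ± 0.45 (chromosome 21, 65128697 to 65132148; gene-level adjusted p = 0.00843), and neither of these circRNAs passed alone (adjusted p = 0.0799 and 0.398). Neither gene passed in a fit that left out fetus 1, fetus 2 or fetus 3 (adjusted p = 0.0575 or more in ACTN2, whose 3-exon circRNA then missed the filter, and 0.0541 or more in LOC102168946). With the replicate number as a block they did not pass either (adjusted p = 0.0623 and 0.125), nor did LOC102168946 by the Simes test (adjusted p = 0.173). The test for unequal change (edgeR's diffSpliceDGE, gene-level F test) covered 361 host genes with at least 2 tested circRNAs, and 21 passed. MLIP (adjusted p = 1.37e-08), FOXJ3 (adjusted p = 3.30e-06) and MYO9A, an unconventional myosin (adjusted p = 0.00217), had the smallest p, and each has a circRNA split over a pair of identifiers. Their highest entries had 0 reads in fetus and 1662, 80 and 112 in kid. The lowest entries were the partners in MLIP and FOXJ3, and in MYO9A another circRNA (chromosome 10, 82495723 to 82505196; log2 fold change -1.08 ± 0.70). With pairs added, 32 of 376 host genes passed: MLIP still did (adjusted p = 6.74e-04), while FOXJ3 (adjusted p = 0.812) and MYO9A (adjusted p = 0.662) did not. MYO9A also did not pass without fetus 3 (adjusted p = 0.0704) or without any 1 kid library. The number of calls was 5 (without fetus 2) to 13 (without kid 2) when 1 library was left out, and 6 with the Simes test.

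Whole libraries were compared by the number of circRNAs detected and by the total and the make-up of their back-splice reads. With each library thinned to 33222 reads, the number of circRNAs with at least 2 reads was 4312 ± 53.0 (SD, n = 3) in fetus and 3681 ± 89.7 (SD, n = 3) in kid (exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 libraries can give). Counting circRNAs with at least 1 read after thinning, there were 7173 ± 366 (SD, n = 3) in fetus and 6638 ± 670.3 (SD, n = 3) in kid, and the stages overlapped (exact permutation p = 0.4). Without thinning the order of the means turned, with 798 more in kid, and the stages overlapped (exact permutation p = 0.5). The 10 most abundant circRNAs of a library took 8.35% to 8.85% of its back-splice reads in fetus and 12.6% to 17.5% in kid. Back-splice reads scaled as CPM of the valid reads were 1057 ± 135 (SD, n = 3) in fetus and 1264 ± 331 (SD, n = 3) in kid (exact permutation p = 0.4), a difference within the spread between libraries. The difference of 207 became 397 without kid 2, which had 883, 97.5 without kid 1, 125 without kid 3 and 136 without fetus 2. Among libraries with over 80% valid reads, fetus 3 had 4282 circRNAs detected, against 3578 to 3736 in kid, and a scaled total of 1186; 1 fetus library is too few for a test there.

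The intronic share of back-splice reads was higher in kid, with 5.03 ± 0.548% (SD, n = 3) in fetus and 8.81 ± 0.354% (SD, n = 3) in kid and no overlap between stages (exact permutation p = 0.1). Fetus 3, the fetus library with over 80% valid reads, had 5.50% and the lowest kid library 8.60%. Without the 10 intronic circRNAs with the most reads, led by that of HCFC1R1, the difference was 1.27 percentage points in place of 3.79. The exonic share was 90.2 ± 0.259% (SD, n = 3) in fetus and 85.5 ± 2.38% (SD, n = 3) in kid (exact permutation p = 0.1), and no p below 0.1 is possible here. Kid minus fetus was -4.77 points, -2.43 without the 10 intronic circRNAs, -2.32 without the circRNAs of the myosin heavy chain cluster and -2.73 as a share of detected circRNAs. The intergenic share was 4.75 ± 0.313% (SD, n = 3) in fetus and 5.73 ± 2.57% (SD, n = 3) in kid (exact permutation p = 0.9), with 8.67% in kid 2. There the difference was 0.985 points, -1.72 without the myosin cluster (4.68 ± 0.298% in fetus and 2.96 ± 0.339% in kid, no overlap, exact permutation p = 0.1), -0.0509 as a share of detected circRNAs, -0.483 without kid 2, 1.53 without kid 1 and 1.91 without kid 3. The read-weighted median circRNA spanned 6142 ± 309.6 bases (SD, n = 3) in fetus and 6109 ± 214 bases (SD, n = 3) in kid (exact permutation p = 0.9), and the median exonic circRNA had 3 exons in each of the 6 libraries. The span's difference of -33 bases lay within the spread between libraries, and became -185 without fetus 2, 124 without fetus 3, -148 without kid 1, 64.8 without kid 2 and -16.2 without kid 3. The spliced length of exonic circRNAs was 393 ± 7.51 bases (SD, n = 3) in fetus and 376 ± 11.2 bases (SD, n = 3) in kid (exact permutation p = 0.1). This difference was -10.7 bases without kid 2 in place of -17, and turned without weighting by reads, to 408 bases in fetus and 410 bases in kid (exact permutation p = 0.9).

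**Figure D5:**
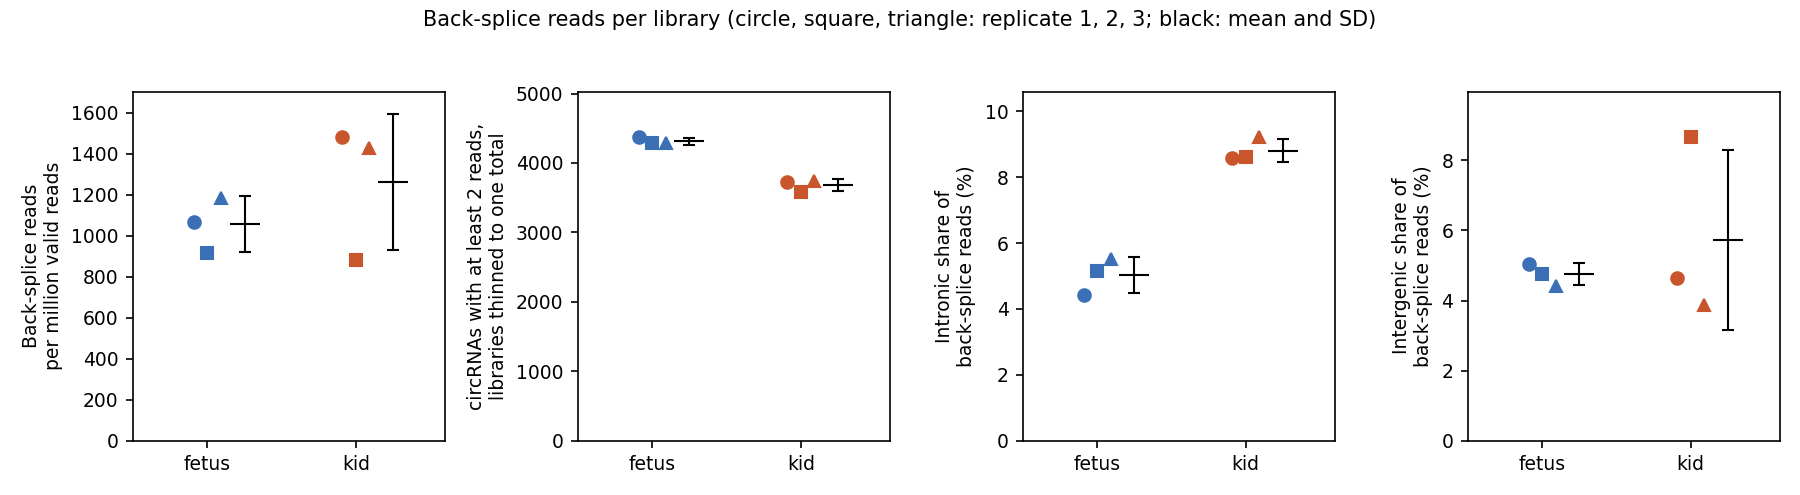
Values per library for the 3 fetus (blue) and 3 kid (red) libraries, with mean and SD in black: back-splice reads as CPM of valid reads, circRNAs with at least 2 reads after thinning, and the intronic and intergenic shares of back-splice reads in percent. The stages do not overlap in circRNAs detected and in the intronic share, and the intergenic share of kid 2 reaches 8.67%.

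The authors' deposited table of fetus against kid marks 831 circRNAs as significant, 486 higher in kid and 345 higher in fetus. Each has a p under 0.05 and an absolute log2 fold change over 1 in that table, and 198 have a q under 0.05 there. Of the 831, 394 did not reach 5 reads in 3 libraries and were not tested here, 437 were, and 216 passed with the same direction. Of the 198 with a q under 0.05, 155 passed. The log2 fold changes of the deposited table and of the edgeR fit correlated across 1852 circRNAs (Pearson r = 0.998, Spearman rho = 0.997), which come from the same reads and are not independent replicates. Of the 831, 126 belong to a pair of identifiers 1 base apart, and 77 of these have no read in any library of one stage.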

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

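The fits with pairs added, the expression file's counts, host names as in the files, exonic circRNAs only, libraries with over 80% valid reads, the read total implied by SRPBM and shares without the myosin cluster or the most abundant intronic circRNAs were chosen after the results were seen; the others were fixed before. The counts of circRNAs and host genes stayed within 1.5 times the reported ones with median-of-ratios size factors, no TMM, other read filters, a 2-fold minimum, DESeq2 and the expression file's counts. For circRNAs they also did so with pairs added and both limma fits, and for host genes with host names as in the files, exonic circRNAs only and the replicate block. Scaled to valid reads, 137 (90 higher and 47 lower) circRNAs and 200 (122 higher and 78 lower) host genes passed. An adjusted p of 0.01 left 72 (53 higher and 19 lower) and 167 (101 higher and 66 lower). DESeq2 called 94 host genes lower, and limma with the smaller pseudocount 57 circRNAs lower. Host names as in the files gave 87 host genes lower. Fetus 3 against the 3 kid libraries, where the lone fetus library is assumed to vary like the kid libraries, gave 8 (6 higher and 2 lower) circRNAs and 68 (51 higher and 17 lower) host genes. Unequal change was called in 9 host genes at a minimum of 10 reads, 6 with Simes and 32 with pairs added. fry called 7 lists. A stricter threshold lowers the counts by construction; for the other settings the cause was not tested.

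With 1 library left out, circRNA calls ranged from 85 to 135, higher from 56 to 109 and lower from 18 to 68. Host gene calls ranged from 184 to 248, higher from 110 to 154 and lower from 57 to 108, and calls of unequal change from 5 to 13. Part of the loss follows from the read filter. Without fetus 1, for example, 191 of the 226 circRNAs and 302 of the 337 host genes that passed in the full fit were tested. List calls ranged from 0 to 1: without kid 2 the hosts from muscle studies passed (adjusted p = 0.0253, against up to 0.395 over its alternatives). Of 28 named circRNAs that passed, 14 passed in all 6 of these fits, and of 72 named host genes 35; several of the rest entered 3 fits only, because a stage with few reads needs all libraries of the other stage to reach the filter. Apart from the pairs of MLIP and FOXJ3, whose members lose their own values when added, no named circRNA or host gene that passed changed sign in any alternative tried (0 and 0). Where stages do not overlap, this is fixed in advance for fits that only leave out libraries. Across alternatives the 32 named circRNAs kept direction and side of the threshold in 555 comparisons, passed newly in 7 (circRNA6203 of LOC106503383 in each), no longer passed in 29 and turned in 8. For 81 named host genes these numbers were 1197, 3, 233 and 2, for 18 lists 228, 8, 0 and 9, and for 5 genes with unequal change 39, 0, 15 and 0. Signs that changed belonged to values that had not passed. circRNA2475 of ZEB1 stood at -0.12 without TMM, -0.0188 at a minimum of 10 reads, -0.18 in libraries with over 80% valid reads and -0.0170 to 0.18 with 1 library left out. circRNA1756 of MYBPC1 stood at 0.0130 scaled to valid reads, 0.0855 without a read filter and -0.37 to 0.12 with 1 library left out. THBS4 ranged from -0.22 to 0.71 with 1 library left out, and UTRN stood at 0.12 with host names as in the files.

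Uncalled lists whose direction turned had camera adjusted p of 0.800 to 0.940 (WNT), 0.800 to 0.955 (widely conserved hosts), 0.800 to 0.940 (TGF-beta), 0.646 to 0.940 (chromatin) and 0.646 to 0.940 (myogenic regulators) with 1 library left out. In the libraries with over 80% valid reads, the myogenic regulators stood at 0.965. Among values per library, circRNAs detected differed by 798 without thinning, which is not corrected for depth. The intergenic share differed by -0.0509 points as a share of detected circRNAs, -1.72 without the myosin cluster and -0.483 to 1.91 with 1 library left out. The genomic span differed by -185 to 124 bases with 1 library left out, and the spliced length by 1.67 without weighting by reads; the cause was not tested.

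The correlation of fetus and kid libraries of one replicate number, after removing stage means, was 0.0134, 0.0316 and -0.0432 for numbers 1, 2 and 3. No pairing by number was seen in these values, but with 3 libraries per stage they cannot exclude one. With the number as a block, 89 (62 higher and 27 lower) circRNAs, 318 (183 higher and 135 lower) host genes and 3 host genes with unequal change passed, and 0 lists; the block takes 2 degrees of freedom from 4. Depth limits single circRNAs: 8736 of 25500, counted as listed, had 1 read.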

Other observations

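The genes and circRNAs named here and the tests of pairs of identifiers, of the myosin cluster and of the intronic share were chosen after the results were seen; the splits of the libraries were fixed before. Several host genes outside the gene lists changed as strongly as those within them. HCFC1R1, whose product regulates a transcriptional cofactor, had the smallest p of all host genes, with 3715 ± 1027 CPM in fetus and 29343 ± 2128 CPM in kid (log2 fold change 2.98 ± 0.19, adjusted p = 1.15e-09). Most of its reads came from the intronic circRNA described above, 467 of 491 in fetus and 4467 of 4944 in kid. MLIP, with all its circRNAs added, stood at 2951 ± 733 CPM in fetus and 16302 ± 1715 CPM in kid (log2 fold change 2.47 ± 0.19, adjusted p = 1.53e-08), and ANO5, a gene of muscle membrane repair, at 485 ± 104 CPM in fetus and 6144 ± 2354 CPM in kid (log2 fold change 3.64 ± 0.30, adjusted p = 2.06e-08). The circRNA of ANO5 described above held 59 of the 65 ANO5 reads in fetus and 1065 of 1136 in kid. ZNRF1, a ubiquitin ligase gene, had 0 reads in fetus and 132 in kid, at least 37.1-fold higher against a floor of 3 reads over the group (adjusted p = 7.84e-06). SNAP91, a gene of clathrin coats, was lower in kid, with 1591 ± 289 CPM in fetus and 328 ± 58.2 CPM in kid (log2 fold change -2.28 ± 0.29, adjusted p = 1.24e-05). P3H2, an enzyme that modifies collagen, stood at 938 ± 292 CPM in fetus and 112 ± 33.1 CPM in kid (log2 fold change -2.98 ± 0.40, adjusted p = 2.23e-05), and PHLPP1, a phosphatase that acts on AKT, at 2991 ± 704 CPM in fetus and 882 ± 271 CPM in kid (log2 fold change -1.75 ± 0.26, adjusted p = 7.58e-05).

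Neighbouring circRNAs on chromosome 21 changed in different directions. A circRNA of LOC102191280 with 4 exons (64998803 to 65014965) was higher in kid (log2 fold change 3.12 ± 0.69, adjusted p = 0.0190). It did not pass without fetus 2 or kid 2 (highest adjusted p = 0.0954), and its log2 fold change was 4.55 without fetus 3. A circRNA of LOC102168946 (65120408 to 65127781) was lower (log2 fold change -1.81 ± 0.40, adjusted p = 0.0179), and it passed in 3 of 6 fits, without kid 1, kid 2 or kid 3 (adjusted p = 0.0337 to 0.0672). With the replicate number as a block it did not pass either (adjusted p = 0.0821). A circRNA of no host gene (65197448 to 65198138) was lower (log2 fold change -1.76 ± 0.33, adjusted p = 0.0104), and it did not pass without fetus 2 (highest adjusted p = 0.0530). Another of no host gene (65156181 to 65160781) did not pass (log2 fold change 0.27 ± 0.17, adjusted p = 0.363). In fetus 3 alone against the 3 kid libraries the first 3 did not pass (adjusted p = 0.148 to 0.169).

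Pairs of exonic circRNAs 1 base apart make up 13.1% of exonic circRNAs and 10.2% of back-splice reads. A choice of splice site that differs between stages is argued against: of 272 pairs seen in all 6 libraries, 1.47% used 1 member in every fetus library and the other in every kid library, against 3.23% if each library picked at random. Both members were counted in the same library 0 times, against 823 expected if the members took their libraries at random. This is consistent with 1 junction counted under 2 identifiers, one per library, and calls on a single member of a pair, as in MLIP and FOXJ3, may then follow the naming. The splice sites themselves were not examined, since no genome sequence was used. Intronic entries were not searched for pairs, and this includes the one of PPP1R12B, which had no read in fetus. The abundant intronic circRNA of HCFC1R1 has a neighbouring entry that starts 1 base earlier, at 2320769. Both had reads in all 6 libraries and were tested as separate circRNAs.

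The 26 intergenic circRNAs that start and end in different genes of the myosin heavy chain cluster on chromosome 19 took 0.0736 ± 0.0244% (SD, n = 3) of back-splice reads in fetus and 2.86 ± 2.42% (SD, n = 3) in kid, from 0.919% to 5.57%. Library depth is argued against, since their mean reads were 53.7 times as many in kid and the back-splice totals 1.54 times. Of all back-splice reads of the cluster, 98.2% joined different genes and 88 reads lay within single genes, consistent with reads joined between neighbouring genes of similar sequence. Circles from read-through transcripts predict the same crossing and stay open, as does a difference in myosin transcription between stages, untested here. The next most abundant of them (29183032 to 29238683) had 4 and 362 reads (adjusted p = 6.34e-04, log2 fold change 6.02, 5.29 without fetus 3; adjusted p = 0.0734 with fetus 3 alone), while one joining MYH8 to LOC102181716 had 12, 16 and 14 reads in fetus and 0, 0 and 3 in kid.

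The intronic share of back-splice reads was larger in kid. A few abundant intronic circRNAs are argued against as the whole cause, since without the 10 with the most reads the mean share was still 1.33 times as large, and the lowest kid library (4.90%) lay above the highest fetus library (4.21%). Without these 10, however, most of the difference in percentage points was gone, as given above. The share of valid reads, which was low in fetus 1 and fetus 2, cannot be told apart from stage: fetus 3, with over 80% valid reads, had an intronic share of 5.50%, below the lowest kid library with 8.60%, but is a single library. A difference in intron turnover between stages is open and was not tested.

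The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 226 circRNAs against at most 3 in any other, 337 host genes against 0, and 21 host genes with unequal change against 2; in each case 1 split, the real one, gave as many. For lists it gave 0 against at most 2, so that all 10 splits gave as many.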
